A study of Aspergillus fumigatus with 12 samples.

How the data were processed

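RNA from hyphae of Aspergillus fumigatus strain CEA10 was sequenced in 12 libraries, 3 at each of 0, 15, 30 and 75 min of an O2 shift in a fermenter. Per the labels' protocols, culture samples were filtered and frozen, total RNA was extracted, and randomly primed Illumina cDNA libraries were made from fragmented polyadenylated RNA. Per the submitters' processing notes, TopHat2 2.0.6 and HTSeq were used, with no role or order given; the genome build, the annotation, the counting settings and any use of strand are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical gene copies therefore cannot be told apart here. Group, time, saturation and replicate letter were taken from the sample titles and labels.

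The authors deposited a workbook with 2 sheets whose names are exchanged relative to their content. The sheet called counts holds RPKM values, deposited by the authors as reads scaled to gene length and to the library total. The sheet called RPKM holds whole-number counts of reads per gene, deposited by the authors without normalization. Each sheet was used for what its values are. Dividing counts by RPKM gave a gene length for the 10018 genes with a read in any library, and 100% of these lengths were within 0.001 bp of a whole number; 25.6% were multiples of 3. It also gave the library totals that the authors' RPKM were scaled to, between 8370734 and 38794687 reads, of which 15.5% to 20.3% were not in the gene counts. The count table has 0 value columns beyond those of the 12 libraries.

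None of the 10160 gene identifiers (0 matched) occurs among the 10086 genes of the reference table given for strain Af293, and the files do not pair identifiers with names. Gene names, descriptions and coordinates were therefore not used here, and the gene lists and named marker genes fixed before the data were examined were not run. The gene rule, also fixed then, took for each comparison the 2 largest rises and the 2 largest falls among genes with an adjusted p under 0.05, a fold of 2 or more, a mean of at least 10 CPM in the higher group and no overlap between the 3 libraries of one group and the 3 of the other, of which 10% arise by chance for 3 against 3. Identifiers are printed only for the 4 genes that this rule took at 15 min. Sets of genes by calls, by level, by length and by identifier order were chosen after the data were seen.

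Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, by group), which kept 8746. Libraries were scaled by TMM, whose factors ran from 0.854 to 0.925 at 15 min and from 1.08 to 1.09 at 30 min, against 0.962 to 1.01 at 0 min and 1.05 to 1.06 at 75 min. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, and 5 contrasts were tested: 15 against 0, 30 against 0, 30 against 15, 75 against 30 and 75 against 0 min. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.233. CPM are TMM-scaled, and log2 CPM had a prior count of 2. Standard errors are on the log2 scale. The smallest exact permutation p for 3 against 3 libraries is 0.1, so single genes were judged by the model that shares the spread across genes. Separate cultures are not stated outright for the replicate letters, so p-values measure the spread between these samples. Replicates of a group differed by far more than counting noise (chi-square per gene of 27.2 to 119), so no library was treated as a duplicate.

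Whether the letters pair the libraries was checked by correlating deviations from the group means across genes. All 18 pairs with the same letter correlated positively, at 0.16 to 0.73, the 36 pairs with different letters at -0.60 to 0.08, and 12 of 12 libraries correlated best with one of their own letter. The labels' protocols describe aliquots drawn from a culture along the shift. The letters were therefore taken as pairing the libraries, and a fit with the replicate block was run as an alternative. The main fit, fixed beforehand without the block, gave the values below unless stated.

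The test was run on simulated counts for the 8746 genes with the real library sizes, for 15 against 0 min. It recovered 8% of 50 genes changed 1.5-fold, 48% of 50 changed 2-fold, 98% of 50 changed 4-fold and 94% of 50 changed 8-fold, and called 7 of 8546 unchanged genes. Far fewer genes were changed in the simulation than were called in the data, which makes its adjusted threshold stricter, so these shares are not the recovery in the data.

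The alternatives tried were DESeq2 1.42.0, RLE, upper quartile and library-size-only scaling, no filter and a filter of 10 CPM in 3 libraries, 2 groups per fit, a minimum fold, the replicate block, limma on log2(RPKM + 1) or log2(RPKM + 0.1), each library left out in turn, and, added after seeing the data, removal of a gene length trend. Comparisons that share libraries were set beside 20 simulated draws of unchanged groups, independent of the letters. A further 20 draws, added after seeing the data, carried the letter effects and the spread of the fit with the replicate block; values are from the draws without letter effects unless stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.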

Results

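Transcript levels were measured by RNA sequencing in hyphae of Aspergillus fumigatus strain CEA10, a mould that can infect the human lung, during a fall and a return of O2 in a stirred fermenter. The 12 libraries fell into 4 groups of 3, marked A, B and C in the sample titles. The first group was taken at 0 min with the medium at 100% O2 saturation. The next groups were taken 15 and 30 min after the gas supply had been switched to bring the saturation to 5%. The last group was taken at 75 min, which was 15 min after full aeration had been restored. The labels of these 12 libraries name none between 30 and 75 min. None of the 12 was kept at 100% saturation without a shift for 15, 30 or 75 min. Changes described below as responses to O2 or to re-aeration therefore cannot be told apart from elapsed time in the fermenter. Between 6974130 and 32781986 reads per library were counted to genes, and 8746 of 10160 genes passed the filter on low counts. Log2 CPM correlated at r = 0.96 to 0.99 across genes within a group and at 0.84 to 0.96 between groups, genes not being independent replicates. The first principal component held 53.1% of the variance and set the 6 low-O2 libraries, all above 20.9, apart from the 6 libraries at 100% saturation, all below -22.9. Genes are given by the files' own identifiers, since none of these matched the reference gene table, and no gene is named by function. Single genes were taken from those called with a fold of 2 or more, a mean of 10 CPM or more in the higher group and no overlap between the libraries of the 2 groups, termed eligible, and the largest changes given are the largest among these. All adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

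The early response to the fall in O2 was read from 15 min against 0 min. Of the 8746 genes tested, 1914 were higher and 1746 lower at 15 min, together 3660 genes or 41.8%. The called genes were a median of 2.21-fold higher or 1.83-fold lower, 1111 rose and 708 fell by 2-fold or more, and 182 rose but 6 fell by 8-fold or more. The largest eligible rise was that of CADAFUBG00004782, a gene of 562 bp, from 0.377 ± 0.375 CPM at 0 min to 36.5 ± 16.9 CPM at 15 min (SD, n = 3), a log2 change of 6.76 with an SE of 0.59 and an adjusted p of 8.25e-06. CADAFUBG00007950 rose from 0.643 ± 0.696 to 56.6 ± 31.3 CPM, a log2 change of 6.60 with an SE of 0.66. At 0 min the first gene had 2, 4 and 9 reads in the 3 libraries and the other 2, 8 and 16, so the size of both folds rests on few reads: without replicate C at 0 min the log2 changes were 7.75 and 7.70. The largest eligible fall was that of CADAFUBG00005007, from 75.0 ± 9.94 to 8.52 ± 4.48 CPM, an 8.97-fold decrease with an adjusted p of 2.20e-05. CADAFUBG00005361 fell from 58.2 ± 15.2 to 7.20 ± 2.51 CPM, an 8.06-fold decrease. Of the called genes, 99.4% moved in their called direction within each of the 3 lettered replicates. The genes were called from these same libraries, which favours a high share. The balance of rises and falls depended on the scaling: with library size as the only scaling 1554 genes were higher and 2357 lower, so that 39.7% of the called genes were higher in place of 52.3%, and with upper quartile scaling 45.2% (1686 against 2044).

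**Figure D1:**
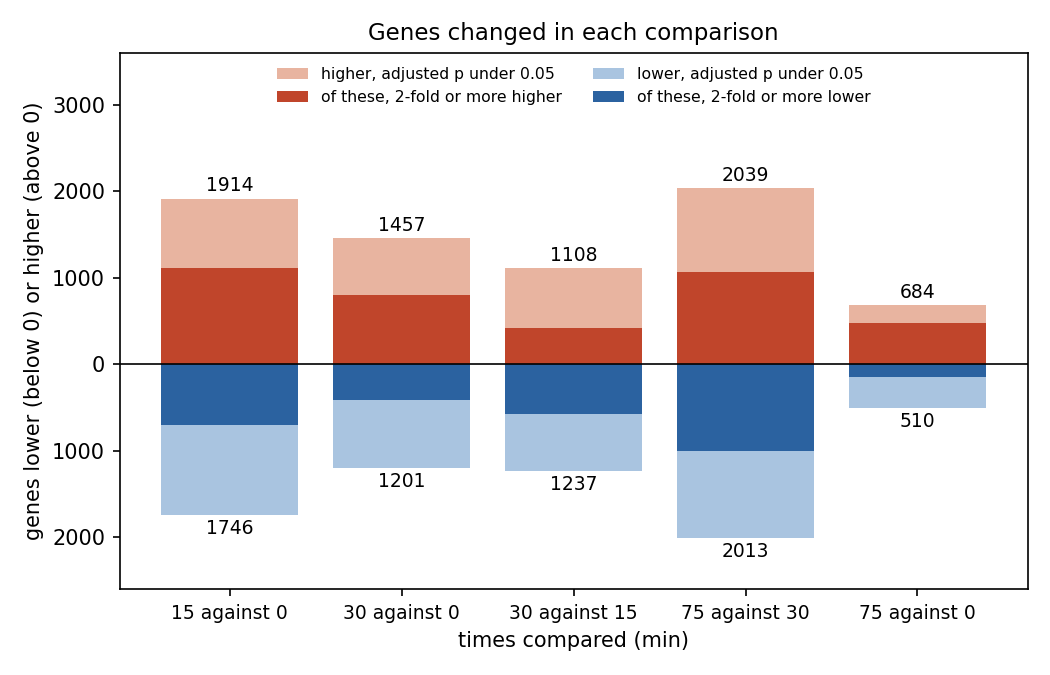
Number of genes called higher (above 0) and lower (below 0) in each of the 5 comparisons of times in minutes, from edgeR's quasi-likelihood test at an adjusted p under 0.05, with the genes changed by 2-fold or more in the darker shade. The comparison of 75 with 30 min has the most calls (2039 higher, 2013 lower) and that of 75 with 0 min the fewest (684 higher, 510 lower), under the TMM scaling; the split into higher and lower differs with other scalings.

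After 30 min at low O2, 1457 genes were higher and 1201 lower than at 0 min, together 2658 genes or 30.4%. Of these, 802 rose and 410 fell by 2-fold or more. CADAFUBG00007950 and CADAFUBG00004782 again had the largest eligible rises, to 38.1 ± 1.71 and 21.0 ± 1.66 CPM (SD, n = 3), or log2 changes of 6.03 and 5.95 (7.12 and 6.94 without replicate C at 0 min). The largest eligible fall at this time was in a gene of 3761 bp that went from 479 ± 178 to 29.2 ± 4.87 CPM, a 16.4-fold decrease with an adjusted p of 2.63e-05. The next eligible fall was in a gene of 1026 bp that went from 102 ± 10.2 to 12.0 ± 4.93 CPM, an 8.57-fold decrease. CADAFUBG00005007 and CADAFUBG00005361 stood at 38.1 ± 8.87 and 28.0 ± 8.87 CPM, lower than at 0 min with log2 changes of -0.98 and -1.06 and adjusted p of 0.025 and 0.037; both calls were lost under several alternatives, with adjusted p of 0.051 to 0.202 and 0.063 to 0.210 where lost. Among the 50 most abundant genes, which held 17.3% of the mean CPM, 26 were lower and 3 higher at 30 min than at 0 min, whereas 5 were lower and 9 higher at 15 min. The count of 2658 fell to 1582 without replicate A at 30 min, to 1680 without replicate B at 0 min and to 1709 without replicate B at 30 min. With library size as the only scaling 1867 genes were higher and 757 lower, 71.2% higher in place of 54.8%, whereas with upper quartile scaling 1246 were higher and 1472 lower, 45.8% higher.

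The calls at 15 and 30 min overlapped in direction for 1738 genes, of which 1029 were higher and 709 lower at both times. Independent lists of these sizes would share 319 higher and 240 lower genes. Both comparisons use the same 0 min libraries: unchanged groups simulated against them shared no called gene in 20 draws, and 74 to 109 genes at an unadjusted p under 0.05, where the data had 2398. Since no gene was changed in these draws, low counts follow by design. The counts do not test how far 2 lists of changed genes overlap. The covariance of the log2 changes across genes was 0.695, against 0.0572 in the simulation, or 0.0332 where the simulated libraries also carried the letter effects. In the draws without letter effects, noise in the shared 0 min libraries gave covariances of 0.0527 to 0.0680. This is far below 0.695 and argues against such noise as the main source of the covariance. The 3 libraries at 0 min cannot be divided into 2 parts of at least 2, so separate controls were not used. Only 30 genes were called in opposite directions at the 2 times. The overlap fell to 1121 genes without replicate A at 30 min and to 1026 without replicate B at 0 min.

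The comparison of 30 with 15 min showed what moved on within low O2. Between these times 1108 genes rose and 1237 fell, together 2345 genes or 26.8%. Of the 869 genes that were higher at 15 min and not called at 30 min, 521 were lower at 30 than at 15 min by this test. Of the 1023 genes that were lower at 15 min and not called at 30 min, 495 were higher at 30 than at 15 min. In the opposite pattern, 208 of the 414 genes called higher at 30 and not at 15 min, and 259 of the 476 called lower in that way, also differed from 15 min in that direction. These sets were picked by their calls in the same libraries, which favours such differences, so the shares are descriptive. The largest eligible fall was in a gene that stood at 0.349 ± 0.209 CPM at 0 min, 29.8 ± 13.5 at 15 min and 1.93 ± 0.922 at 30 min (SD, n = 3), a 15.6-fold decrease from 15 to 30 min with an adjusted p of 0.000335. The largest eligible rise was in a gene that went from 0.879 ± 0.393 to 10.3 ± 6.74 CPM, 11.01-fold, having been at 1.07 ± 0.408 at 0 min; its log2 change of 3.46 was 2.76 without replicate A at 30 min. CADAFUBG00005007 and CADAFUBG00005361 rose 4.55-fold and 3.87-fold, with adjusted p of 0.00067 and 0.0030. For CADAFUBG00004782 and CADAFUBG00007950 the log2 differences were -0.81 and -0.58, with adjusted p of 0.173 and 0.402, neither past the threshold. Among the 50 most abundant genes 30 fell and 1 rose, and the falls numbered between 22 and 30 over the 4 scalings. With library size as the only scaling 2545 genes were higher and 703 lower at 30 min, 78.4% higher in place of 47.2%. The count of 2345 fell to 1439 without replicate B at 30 min.

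**Figure D2:**
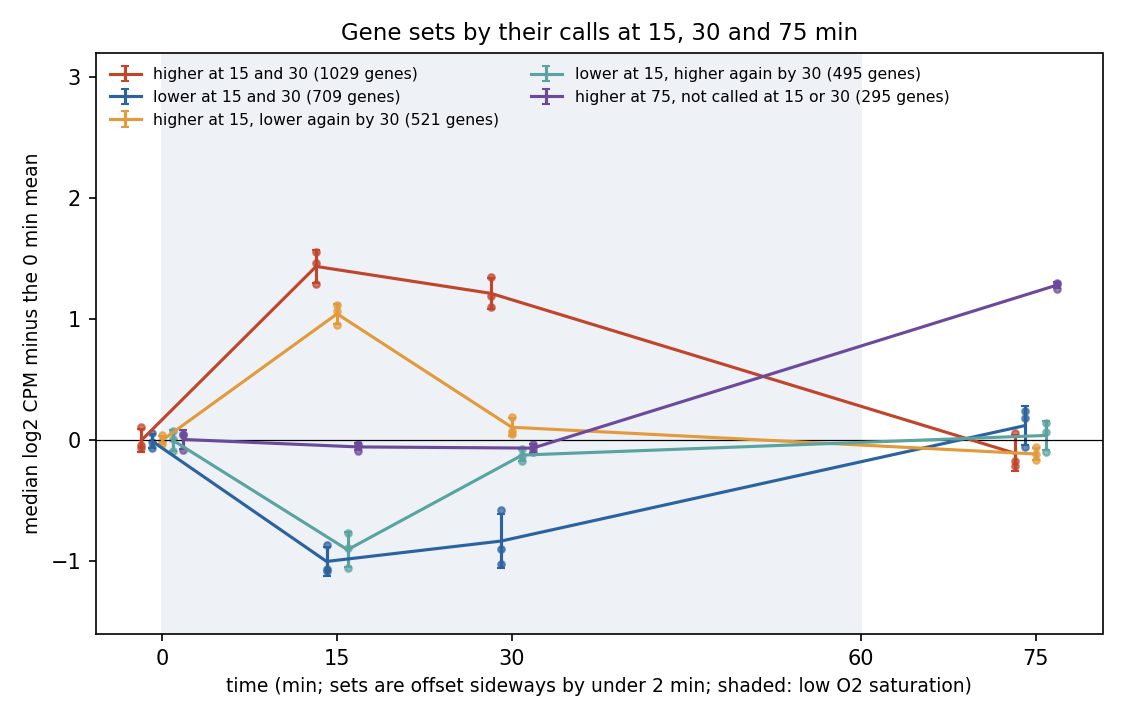
Median log2 CPM of 5 gene sets relative to their mean at 0 min (vertical axis) against time in minutes, with a point per library, lines through the means, and bars of 1 SD over the 3 libraries; no library lies between 30 and 75 min, and the shaded span is low O2. The sets were formed from the calls at these same times, so the picture shows their size and spread and does not test them. The 1029 genes called higher at 15 and 30 min had a mean of 1.44 at 15 min, 1.21 at 30 min and -0.11 at 75 min.

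The response to renewed aeration was read from 75 against 30 min, which also spans the rest of the low-O2 period. In the main fit it had the most calls of the 5 comparisons: 2039 genes were higher and 2013 lower at 75 min, together 4052 genes or 46.3%, of which 1071 rose and 1003 fell by 2-fold or more. With limma on log2(RPKM + 0.1) it had 3949 calls, fewer than the 3970 at 15 against 0 min. Of the 2658 genes called at 30 min, 2115 (79.6%) moved the opposite way between 30 and 75 min, 1169 of them downward and 946 upward. Independent lists would share 335 and 280 such genes. Because both comparisons use the 30 min libraries, unchanged simulated groups gave a covariance of -0.0564 (-0.0333 with letter effects) between the 2 sets of log2 changes, and the data gave -0.685. No called gene was shared in the 20 simulated draws, and 85 to 112 were at an unadjusted p under 0.05, where the data had 2816. Since no gene was changed in the draws, these low counts follow by design and do not test the return. In the draws without letter effects, noise in the shared 30 min libraries gave covariances of -0.0633 to -0.0506, against -0.685 in the data. This argues against such noise as the main source of the covariance. The 3 libraries at 30 min cannot be divided in this way either, so separate ones were not used. CADAFUBG00004782 fell 34.4-fold and CADAFUBG00007950 25.02-fold, to 0.711 ± 0.323 and 1.67 ± 0.928 CPM (SD, n = 3). Neither was called against 0 min by edgeR (adjusted p of 0.483 and 0.232). Their log2 changes from 0 to 75 min were 0.85 (SE 0.72) and 1.38 (SE 0.71) and rest on few reads, so a full return is not shown. CADAFUBG00005007 rose 2.25-fold to 85.6 ± 5.48 CPM and CADAFUBG00005361 2.62-fold to 73.2 ± 31.1 CPM. The largest eligible fall was in a gene at 42.1 ± 14.5 CPM at 0 min, 3415 ± 245 at 15 min, 940 ± 77.5 at 30 min and 10.95 ± 1.23 at 75 min, an 86.1-fold decrease between 30 and 75 min with an adjusted p of 1.26e-07. The next eligible fall was in a gene at 17.3 ± 7.58, 1566 ± 430, 822 ± 64.4 and 10.9 ± 3.88 CPM at the same 4 times. The largest eligible rise was in a gene of 829 bp that went from 0.384 ± 0.022 to 43.4 ± 31.2 CPM, a log2 change of 6.78, or 6.10 without replicate C at 75 min. Among the 50 most abundant genes 19 rose and 9 fell. With upper quartile scaling 2625 genes were higher and 1589 lower, 62.3% higher in place of 50.3%, and with library size only 46.7% (1851 against 2115). The 2115 genes fell to 1258 without replicate A at 30 min and to 1375 without replicate B at 30 min.

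**Figure D3:**
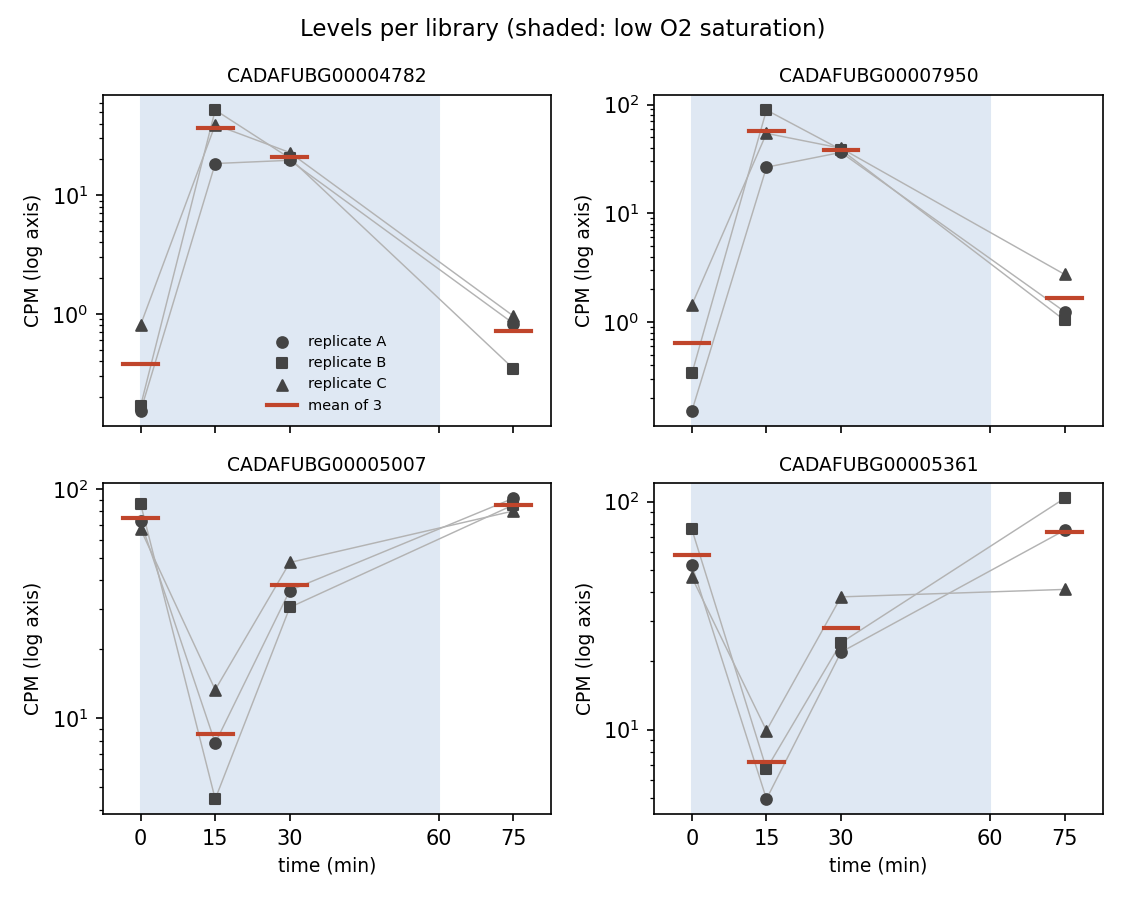
Level in CPM (log axis) against time in minutes for the 2 genes with the largest eligible rises and the 2 with the largest eligible falls at 15 min, 1 point per library, with thin lines joining libraries of a replicate letter and a bar at the mean of 3; no library lies between 30 and 75 min, and the shaded span is low O2. CADAFUBG00004782 and CADAFUBG00007950 lie above 18 CPM in all 6 low-O2 libraries and below 3 CPM in the other 6.

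Whether expression 15 min after re-aeration differed from that before the shift was read from 75 against 0 min, both at 100% saturation. Here 684 genes were higher and 510 lower, together 1194 genes or 13.7%, of which 473 rose and 143 fell by 2-fold or more. Of the 2658 genes called at 30 min, 2132 (80.2%) were not called at 75 min, 257 were still called the same way and 269 the opposite way. By direction, 174 genes were higher and 83 lower at both times, where independent lists would share 114 and 70.0, and 171 were higher at 30 and lower at 75 min and 98 the reverse, where independent lists would share 84.96 and 93.9. With the replicate letter as a block 1908 genes were called, 1063 higher and 845 lower. Of 3370 genes then called at 30 min, 2399 (71.2%) were not called at 75 min, 502 were called the same way and 469 the opposite way. A further 295 genes were higher at 75 min without being called at 15 or 30 min, and 262 of these were also higher than at 30 min. In the same way 156 were lower, 123 of them also lower than at 30 min. Both sets were picked by calls in the same libraries, which favours these differences from 30 min. The largest eligible rise was in the same 829 bp gene as from 30 min, from 0.567 ± 0.236 to 43.4 ± 31.2 CPM (SD, n = 3), a log2 change of 6.33 with an SE of 0.66 and an adjusted p of 0.000172 (a log2 change of 5.64 without replicate C at 75 min). The largest eligible fall was in a gene at 117 ± 58.9 CPM at 0 min, 2004 ± 514 at 15 min, 624 ± 187 at 30 min and 16.6 ± 8.001 at 75 min, a 7.17-fold decrease from 0 to 75 min, and 6 called genes that were not eligible fell more. The next eligible fall was in a gene at 1212 ± 22.8, 2560 ± 1046, 1119 ± 92.7 and 183 ± 51.2 CPM. The covariance of log2 changes at 30 and 75 min, which share the 0 min libraries, was 0.0841, against 0.0572 (0.0522 to 0.0636) in the simulation without letter effects and 0.0332 (0.0292 to 0.0386) in that with them. The correlation was 0.134, below the 0.499 (0.469 to 0.526) and 0.493 (0.460 to 0.539) of the same simulations. Noise in the shared libraries alone sets the simulated correlations, and changes of genes dilute them. The lower correlation therefore does not show that the changes at 30 and 75 min were less alike. With upper quartile scaling 69.0% of the called genes were higher (792 against 356), and with library size only 72.8% (860 against 321), in place of 57.3%. The count of 1194 fell to 676 and 637 without replicates A and B at 0 min, and to 668 and 686 without replicates A and B at 75 min. Over all 5 comparisons 6005 genes were called at least once, 91 in all 5 and 2741 in none.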

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

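For the 6 genes with the largest eligible changes at 15 or 30 min, the effect of low O2 was compared between the times by the test of 30 against 15 min, and 4 passed it. CADAFUBG00005007 had a log2 change of -3.16 at 15 min and -0.98 at 30 min, and the difference was 2.19 (edgeR adjusted p of 0.00067, in that direction in 3 of 3 replicates). For CADAFUBG00005361 these were -3.01 and -1.06 and the difference was 1.95 (adjusted p of 0.0030, 3 of 3 replicates). The gene with the largest eligible fall at 30 min went the other way: its log2 change was -1.61 at 15 min and -4.04 at 30 min, a difference of -2.43 (adjusted p of 0.00037, 3 of 3 replicates). The gene with the next eligible fall at 30 min had -1.55 and -3.10, a difference of -1.55 (adjusted p of 0.0017, 3 of 3 replicates). Each gene was picked for an extreme fall at 1 of the 2 times and was weaker at the other, the direction that this selection favours, which tends to overstate the differences; its size was not measured. With the gene length trend removed, chosen after seeing the data, the differences for CADAFUBG00005007 and CADAFUBG00005361 were 2.17 and 1.90.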

How the results depend on the processing

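The alternatives with a gene length trend removed were chosen after seeing the data. Over all settings run, the counts at 15 against 0 min and 75 against 30 min stayed within 1.5 times their values, except with a minimum fold. Requiring a fold of 2 or more left 1819 genes at 15 min, 1212 at 30 min, 999 for 30 against 15 min, 2074 for 75 against 30 min, 616 for 75 against 0 min, 728 in the overlap and 919 of those that went back. Testing against 1.5-fold (glmTreat) left 1620, 873, 629, 1863, 278, 495 and 668 in the same order; both are stricter by construction. With the replicate block 4219 genes were called at 15 min, 3370 at 30 min, 2981 for 30 against 15 min and 4630 for 75 against 30 min. Each count exceeded that of the main fit, so counts of genes not called depend on leaving out the block. The replicate block moved the count at 75 against 0 min from 1194 to 1908, or 2155 with the length trend also removed. It moved no other count of these 7 by over 1.5 times, and the cause was not tested. Leaving out 1 library gave 1582 to 2692 at 30 min, 1439 to 2112 for 30 against 15 min, 637 to 1263 for 75 against 0 min, 1026 to 1813 in the overlap and 1258 to 2234 of those that went back, with fewer samples in each fit. Of the values of single genes under the alternatives, 661 kept their direction and side of the threshold, 16 (all for CADAFUBG00005007 and CADAFUBG00005361 at 30 min) lost the call, and 1 changed sign: CADAFUBG00005361 at 75 against 0 min, which was not called, went from 0.33 to -0.0042 without replicate B at 75 min (-0.0042 to 0.62 over the libraries left out); the filter of 10 CPM in 3 libraries removed a pair of genes, which have no value there. limma on log2(RPKM + 1) understates low genes: for CADAFUBG00004782 at 15 min it gave 4.91 in place of 6.76. The alternatives for gene lists were not run, since the lists could not be matched.

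Scaling mattered for the balance of rises and falls. Library size alone moved the median of all tested genes to -0.17 at 15 min, 0.11 at 30 min and 0.28 for 30 against 15 min, and upper quartile scaling to -0.11 at 15 min and 0.16 for 75 against 30 min. Changes close to these sizes have a direction only relative to a scaling. limma on RPKM gave shares of higher calls near those of library size alone: 38.2% to 39.4% at 15 min, 69.2% to 70.9% at 30 min, 77.9% to 78.6% for 30 against 15 min and 73.3% to 76.1% for 75 against 0 min. The smallest library, with 6974130 counts, limits what can be seen of weak genes at 75 min.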

Other observations

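The test of identifier order and the neighbour tests other than that at 15 min were chosen after the results were seen, and the patterns were found in the same data. Genes of low level stood apart at 75 min. Tested genes were put into 5 classes of equal size by mean level. In the lowest class 275 of 1750 were higher and 14 lower at 75 than at 0 min by edgeR, with a median log2 change of 0.39, while in the highest class 69 of 1749 were higher and 203 lower, with a median of -0.13. The medians of the lowest class were 0.39 to 0.49 over the 4 scalings, and those of the highest class -0.13 to -0.04. At 30 min the gap between these medians was 0.0025. No gene was at 10 CPM or more in each 0 min library and under 1 CPM in each library of another time, whereas 9 genes were under 1 CPM in each 0 min library and at 10 CPM or more in each library at 15 min, 1 at 30 min and 1 at 75 min.

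Unequal depth was tested against this level pattern by thinning all libraries to the smallest. The gap between the lowest and highest class was then 0.538 (0.525 to 0.554 in 5 draws), against 0.520 before, which argues against depth. A single replicate is argued against too: the gap was 0.536, 0.429 and 0.588 within replicates A, B and C, the lowest being 0.429. Background reads spread evenly over the genome stay open. They would have left few genes below the median gain of 0.510 RPKM at 75 min; 8% of the lowest class lay below it, between the bounds of 5% and 20% set beforehand. The share of the RPKM library totals that was not in the gene counts was 16.7 ± 1.24% at 75 min and 17.6 ± 0.81% at 0 min (SD, n = 3). What these reads are is not given in the sources used here, so this share is not a measure of background. In the lowest class 19.4% had a lower RPKM at 75 min. Neither the share nor this percentage was given a bound. The biological explanation, a change after re-aeration that raises weakly expressed genes, is a hypothesis and was not tested further.

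Short genes were higher relative to long genes at 15 min, with median log2 changes of 0.09 in the shortest and -0.15 in the longest of 5 classes of length (-0.05 and -0.29 with library size as the only scaling). At 30 against 15 min, which shares the 15 min libraries, the trend was opposite and larger, with medians of -0.15 and 0.13. The rank correlation of change with length was 0.173 there, against -0.126 at 15 against 0 min. Variation in length bias between libraries may account for the pattern at 15 min. The slope of log2 CPM on log2 length was lower at 15 than at 0 min by 1.95 pooled within-group SD (a difference of -1.9462), just under the bound of 2, although the libraries of the 2 groups did not overlap (exact permutation p of 0.1, the smallest possible). Within the lettered replicates the slope fell in 3 of 3, with a mean difference of -0.127 ± 0.132 (SD, n = 3), with an exact sign-flip p of 0.25, the smallest possible. Most of the difference came from replicate B, at -0.228 against -0.043 and -0.0045 in A and C at 15 min. A bias acting on all genes alike stays open as well: the rank correlation of change with length, across genes, was negative in each of the 5 level classes, the highest being -0.0987. A biological difference between short and long genes at low O2 is therefore not separated from a technical one. With the length trend removed, 3780 genes were called at 15 min in place of 3660, and 3463 of these were shared in direction.

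Genes with consecutive identifiers changed together. The correlation of their log2 changes at 15 min was 0.280 over 8019 pairs, beyond all 2000 shuffles of the identifiers (highest 0.037, p of 5e-04, the smallest they can give), which argues against an order without information; over the 5 comparisons it was 0.260 to 0.325, each with an adjusted p of 5e-04. At 15 min 22 runs of at least 4 consecutive genes rose by 2-fold or more, against a mean of 1.61 and at most 6 in 1000 shuffles. Runs outnumbered those of all shuffles in 9 of 10 combinations of comparison and direction. The exception was falls at 75 against 30 min, with 8 runs and up to 8 in shuffles. Some of the 9 rest on few runs: falls at 75 against 0 min had 1 (at most 0 in shuffles) and rises at 30 against 15 min had 2 (at most 1). The comparisons share libraries, so the 9 are not separate tests. Reads of one gene counted in its neighbour would tie genes of unequal level most. At 15 min the correlation within 2-fold in level minus that over 8-fold apart was -0.0303 (95% bootstrap interval -0.109 to 0.052), so the explanation stays open there, as it does at 30 against 0 min (-0.00025, -0.084 to 0.078) and 75 against 30 min (0.066, -0.0094 to 0.136). At 30 against 15 min it was 0.152 (0.086 to 0.218). At 75 against 0 min, the largest of the 5, it was 0.222 (0.137 to 0.313). There the changes also followed level, with a rank correlation across genes of -0.343. At 30 against 15 min that correlation was -0.038, but the changes still differed by level. In the highest level class 179 genes were higher and 408 lower, and in the middle class 320 and 220. Dependence on level by itself makes genes of like level change alike, so no conclusion is drawn for either of these comparisons. Shared regulation of neighbouring genes may be another explanation, but no coordinates were used here, so the step from identifier order to position was not tested.

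Other splits of the 6 libraries into 3 and 3 were too few for a share under 0.05 in any comparison, since there are 10, and in each the real split was the 1 split with as many edgeR calls. The real counts were 3660, 2658, 2345, 4052 and 1194, in the order 15 against 0, 30 against 0, 30 against 15, 75 against 30 and 75 against 0 min, and the highest other split gave 0, 0, 0, 1 and 0. At an unadjusted p under 0.05 the real splits had 4349, 3643, 3371, 4660 and 2500 genes and the highest other splits 771, 552, 1032, 824 and 779. The 3 other splits that part all 3 letter pairs as the real one does gave 0 calls in each comparison, and the 6 that part a single pair gave at most 1. Every other split mixes libraries of both times in each part, so differences between the times widen its spread. Few calls in the other splits follow from this, and they are not used as support.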
